A study of Mus musculus with 12 samples.

How the data were processed

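RNA sequencing values of mouse heart were taken from 1 deposited table of 34714 genes and 12 columns of values. The labels describe 12 samples in 3 groups. In the table, 11 columns carried the name given in a sample's label and were used (4 aPD1_lef, 4 aPD1_veh and 3 IgG_lef), and 1 column matched no label and was not used. Its name differs from that in the label of the fourth IgG_lef sample only in the order of its digits, so it may hold that sample, but the match was not assumed and the sample was not analysed here. Total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit, per the labels' protocols. The unit is not stated in the sources used here: the deposited values were treated as FPKM made by the authors, normalized for length and depth, because they were not whole, their totals differed between libraries, and the lowest value of a gene fell with its exon length (slope -0.483 ± 0.033 SE on log2 scales, 1020 genes). A TPM table from which mitochondrial genes had been left out could not be excluded, and 0 mitochondrially encoded genes were in the table. HISAT2, DESeq2 and the genome build mm10 are named in the submitters' processing notes, without their roles, and the version of the aligner and the program that made the values are not given in the sources used here. All 34714 symbols matched the RefSeq annotation of GRCm38.p6, from which coordinates were taken.

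Whole read counts could not be recovered. At the best step for each library, 12.6% to 17.2% of values lay within 0.05 of a whole number of steps, against 10% by chance. The depth is therefore unknown, and no counting interval or detection floor is given. The design fixed before the data were examined planned a negative binomial test for whole read numbers and, if the table held none, limma on log2 values, which was therefore used.

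Genes with a value of 1 or more in at least 4 libraries were kept, which left 12005 genes. In every library used, 10347 genes were at 0. With 3 IgG_lef libraries, a gene that reached 1 only in IgG_lef could not pass this filter. A gene that reached 1 only in the 4 libraries of aPD1_lef or of aPD1_veh could. Values were analysed as log2(value + 1), so the log2 changes understate the change of genes with low values. Ratios of group means are on the scale of the values. One model of the 3 groups was fitted to all 11 libraries with limma 3.58.1 (lmFit, then eBayes with trend and robust fitting) in R 4.3.3 with statmod 1.5.0, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. No scaling was added to that of the authors. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

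The groups, comparisons, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except for alternatives described as added. There were 36 gene lists of pathways and cell type markers, of which 28 had at least 3 measured genes and were tested with limma's camera (preset correlation 0.01), adjusted over the lists of a comparison. Beside it, camera was run with an estimated correlation, and fry tested whether the genes of a list moved, on balance, one way. For each list, genes were also adjusted over the list alone. The genes named were, for each comparison, the 8 with the largest increase and the 8 with the largest decrease among those called with a mean value of at least 1 and group values that did not overlap, up to 4 genes with the smallest p of each list called and of 8 lists fixed for this in any case, and 10 genes fixed by name. Gene models and predicted genes were skipped. Some genes that meet this rule are not reported here. Genes named outside this rule are described as chosen after their values were seen or as the members of a list that did or did not pass. Myl7, Mmp9 in the first comparison, Mt1, Mt2 and Cd3e are such genes in the results.

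The test was checked on simulated values of the same 12005 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. For aPD1_lef against aPD1_veh it recovered 84% and 99% of them, with 7.1% of calls false. For aPD1_veh against IgG_lef it recovered 82% and 95%, with 3.3% false, and for aPD1_lef against IgG_lef 72% and 97%, with 2.9% false. The values were drawn independently for each gene, with the same spread in every group. They therefore lack the correlation between genes and the unequal spread of the groups in these data, where the rates need not hold.

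The alternatives were limma without trend, quantile normalization, scaling every library to one total, a pseudocount of 0.1, no filter on low values, a fit of only the groups compared, a fit without robust weights, the replicate number as a block, and leaving out each library in turn. Median-ratio scaling and leaving out the 3 libraries with atrial transcripts (Myl7 above 10) were added after seeing the data.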

Results

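RNA from mouse heart was sequenced in 3 treatment groups. The labels name aPD1_lef (4 libraries), aPD1_veh (4 libraries) and IgG_lef (3 of the 4 labelled libraries used here). Anti-PD-1 (aPD1) is an antibody that blocks the immune checkpoint receptor PD-1, IgG is its control antibody, and leflunomide (lef) is an immunosuppressant that inhibits dihydroorotate dehydrogenase and also binds the aryl hydrocarbon receptor. The abbreviation veh was read as vehicle. No group labelled IgG with vehicle was analysed here, so aPD1_veh and IgG_lef differ, as labelled, in both antibody and drug. That IgG_lef received the drug rests on its label alone: were it a control without the drug, the second comparison would differ in antibody only and the third in antibody and drug. The labels do not state whether each library came from its own animal, so every p-value measures only the spread between these samples. The deposited values, taken as FPKM, summed to between 393494 (replicate 4) and 413010 in aPD1_lef and between 441935 and 465511 (replicate 4) in aPD1_veh. In IgG_lef they summed to between 413628 and 440748, so the totals of the groups did not overlap. Per library, 11352 to 11922 genes had a value of 1 or more. Read depth is unknown, since whole read counts could not be recovered from the values. Libraries of aPD1_veh correlated with each other across genes at r = 0.986 to 0.992, those of IgG_lef at 0.98 to 0.99 and replicates 1 to 3 of aPD1_lef at 0.978 to 0.992, where genes are not independent replicates. Replicate 4 of aPD1_lef correlated with its group at only 0.91 to 0.95, and its 10 highest genes held 7.64% of its total against 10.95% to 14.05% in the other libraries.

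**Figure D1:**
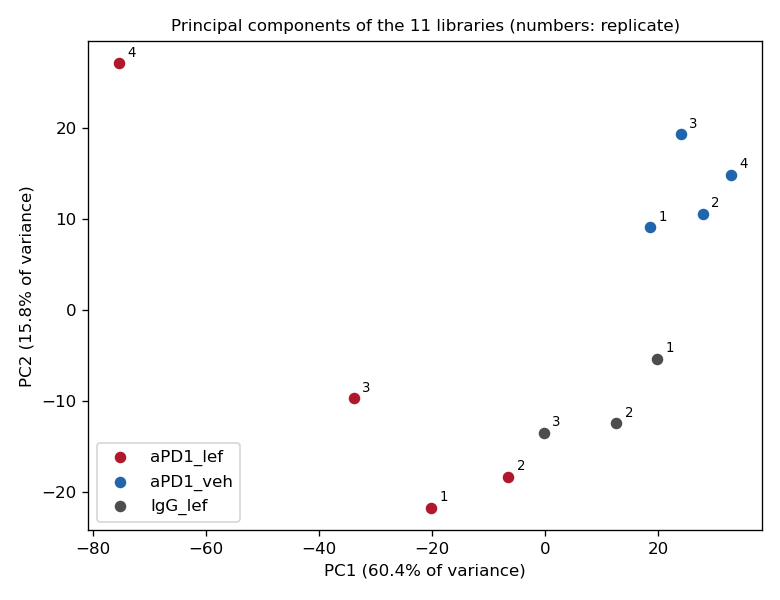
Position of each of the 11 libraries on the first and second principal components of log2(value + 1), with groups by colour. The first component held 60.4% of the variance and the second 15.8%, and aPD1_lef replicate 4 lay at -75.4 on the first.

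The first comparison, between the libraries labelled aPD1_lef and aPD1_veh, asked what leflunomide changed in hearts of mice given anti-PD-1. Of the listed genes of cardiac stress and of scar matrix, 8 of 10 and 15 of 19 were higher in the libraries labelled aPD1_lef, though neither list passed with an estimated correlation (adjusted p = 0.663 for both). Nppa (chromosome 4, 148000722 to 148002074, GRCm38), which encodes the natriuretic peptide released by stretched heart muscle, averaged 4082 ± 1401 FPKM (SD, n = 4) in aPD1_lef and 208.6 ± 261.6 (SD, n = 4) in aPD1_veh, a ratio of 19.6, or 51.4 without aPD1_veh replicate 1. Postn (chromosome 3, 54359267 to 54391041), a matrix protein of activated fibroblasts, averaged 558.4 ± 314.5 against 14.55 ± 5.476 FPKM, a ratio of 38.4. In both genes every aPD1_lef library exceeded every aPD1_veh library.

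Of the 10 measured genes of cardiac stress and fetal expression, 8 rose, none fell and 2 did not pass (8 rose when adjusted over the list alone). Their median log2 change was 2.08, with adjusted p = 0.000551 by camera and adjusted p = 0.663 with an estimated correlation. Nppa rose by 5.05 ± 0.815 (SE) on the log2 scale (adjusted p = 0.00203). Acta1, the skeletal form of actin that reappears in strained heart muscle, rose by 3.23 ± 0.456 (adjusted p = 0.00113). Myh7, the slow myosin heavy chain of the fetal mouse heart, averaged 533.4 ± 176.9 against 147.4 ± 30.77 FPKM, and Xirp2, an actin-binding protein of muscle cell junctions, averaged 137.8 ± 69.16 against 24.39 ± 7.839. Both of these rose, by 1.80 and 2.35 on the log2 scale. Nppb, the second natriuretic peptide, rose by 2.59 ± 0.586 (adjusted p = 0.00934), with values that overlapped between the groups. Without aPD1_veh replicate 1 the ratio of means was 13.9 instead of 7.08 for Acta1 and 8.94 instead of 4.83 for Nppb. The metallothioneins Mt1 and Mt2 were the members that did not pass. Libraries also differed in atrial tissue: the atrial myosin light chain Myl7 stood at 32.5 and 43 FPKM in aPD1_lef replicates 1 and 2 and at 266 in IgG_lef replicate 2, against at most 1.78 in the other libraries. Replicates 3 and 4 of aPD1_lef, with Myl7 under 1, held 5183 and 4866 FPKM of Nppa.

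Of 19 measured fibrosis and matrix genes, 15 rose, 1 fell and 3 did not pass (16 rose and 1 fell when adjusted over the list alone). The median log2 change was 2.91 (adjusted p = 3.04e-07 by camera, and adjusted p = 0.663 with an estimated correlation). Mmp2, a gelatinase that remodels matrix, rose by 2.16 ± 0.139 on the log2 scale (adjusted p = 2.01e-05), from 18.15 ± 1.502 to 85.04 ± 11.35 FPKM. Ccn2, a matricellular growth factor, averaged 495.2 ± 409.5 against 35.91 ± 10.32 FPKM, a ratio of 13.8, or 8.44 without aPD1_lef replicate 4. The gene that fell was the neutrophil and macrophage gelatinase Mmp9, which averaged 0.207 against 1.20 FPKM (a ratio of 0.172, or 0.0661 without aPD1_lef replicate 4). Several matrix genes outside this list were among the largest increases. Thbs4, a matricellular thrombospondin, averaged 175.1 ± 97.43 against 2.58 ± 1.47 FPKM, Cilp, a cartilage matrix protein, 202.3 ± 68.65 against 4.361 ± 3.014, and Comp, an oligomeric matrix protein, 108.4 ± 20.37 against 2.429 ± 1.819. Ltbp2, which binds elastic fibres, averaged 75.97 ± 51.18 against 1.176 ± 0.6931 FPKM. Sprr1a, induced in stressed muscle cells, rose by 4.73 on the log2 scale.

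Markers of fibroblasts moved with the matrix genes. Of 9 measured, 7 rose, none fell and 2 did not pass (8 rose when adjusted over the list alone), with a median log2 change of 0.93 (adjusted p = 0.000103 by camera, and adjusted p = 0.562 with an estimated correlation). Mfap5, a microfibril protein, rose by 3.48 ± 0.376 on the log2 scale (adjusted p = 0.000279), and the collagen-binding proteoglycan Lum averaged 105 ± 15.96 against 32.69 ± 4.849 FPKM. Of 10 measured proliferation genes, 8 rose, none fell and 2 did not pass (10 rose when adjusted over the list alone), with a median of 0.92 (adjusted p = 0.00137 by camera, and adjusted p = 0.663 with an estimated correlation). Mcm6, a subunit of the replicative helicase, averaged 8.937 ± 1.422 against 4.102 ± 0.8644 FPKM.

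Genes of fatty acid oxidation and of oxidative phosphorylation were lower in the libraries labelled aPD1_lef. Of 19 measured genes of fatty acid oxidation, 17 fell, none rose and 2 did not pass (17 fell when adjusted over the list alone), with a median log2 change of -0.998 (adjusted p = 1.51e-09 by camera, and adjusted p = 0.562 with an estimated correlation). Ech1, an enzyme that breaks down unsaturated fatty acids, averaged 418.4 ± 138.4 against 1135 ± 126.7 FPKM and fell by 1.496 ± 0.218 on the log2 scale (adjusted p = 0.00128). Ppargc1a, the coactivator that drives mitochondrial genes, averaged 6.192 ± 1.316 against 15.84 ± 0.8697 FPKM. All 15 measured genes of oxidative phosphorylation fell, also when adjusted over the list alone, with a median of -0.79 (adjusted p = 3.45e-08 by camera, and adjusted p = 0.663 with an estimated correlation). Among them, Sdha of complex II averaged 308.8 ± 86.4 against 587.2 ± 58.56 FPKM and Cox4i1 of complex IV 1363 ± 298.6 against 2409 ± 178.6.

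Of 18 measured sarcomere and calcium handling genes, 6 fell, none rose and 12 did not pass (6 fell when adjusted over the list alone). The median was -0.50 (adjusted p = 0.00401 by camera, and adjusted p = 0.663 with an estimated correlation), and under quantile normalization the call was lost with a median of -0.17 (adjusted p = 0.252). Without aPD1_lef replicate 4 the median was -0.285 (adjusted p = 0.0114), and without the 3 libraries with atrial transcripts -0.785 (adjusted p = 0.000958). Atp2a2, the calcium pump of the sarcoplasmic reticulum, averaged 1400 ± 715.1 against 3203 ± 312.5 FPKM and Tnni3, cardiac troponin I, 1972 ± 768.6 against 4296 ± 530.4. Myh6, the main adult myosin heavy chain of mouse heart, averaged 1626 ± 1090 against 3258 ± 179.4 FPKM (adjusted p = 0.0829, not past the threshold), and its lowest value, 244.2, was in aPD1_lef replicate 4. Among the largest decreases were the carboxylesterase Ces1d, at 7.079 ± 7.955 against 52.75 ± 12.29 FPKM, and Penk, the enkephalin precursor, at 1.338 ± 1.364 against 10.54 ± 1.673. Without aPD1_lef replicate 2 their ratios of means were 0.0699 instead of 0.134 and 0.0754 instead of 0.127. All 6 measured erythroid markers fell, also when adjusted over the list alone (median -1.61, adjusted p = 0.000609 by camera, and adjusted p = 0.663 with an estimated correlation). The beta globin Hbb-bs averaged 1250 ± 84.04 against 3841 ± 850.9 FPKM.

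Of 22 measured interferon response genes, 13 rose in aPD1_lef, none fell and 9 did not pass (13 rose when adjusted over the list alone), with a median of 1.02 (adjusted p = 0.000816 by camera, and adjusted p = 0.663 with an estimated correlation). Without the 3 libraries with atrial transcripts the median was 0.67 (adjusted p = 0.0478). Isg15, an interferon-induced ubiquitin-like protein, averaged 36.99 ± 15.02 against 11.72 ± 3.704 FPKM, and the antiviral synthetase Oas1a 10.61 ± 3.333 against 3.082 ± 0.424. Of 16 markers of monocytes and macrophages, 1 rose and 15 did not pass (1 rose when adjusted over the list alone; adjusted p = 0.35 by camera), and the one that rose was the Fc receptor Fcgr1, at 4.964 ± 1.404 against 1.62 ± 0.3058 FPKM. Only 1 of 18 markers of T and NK cells was measured above the filter, the chemokine Ccl5, at 2.92 ± 1.996 against 2.929 ± 0.5002 FPKM. The T cell receptor component Cd3e averaged 0.173 and 0.143 FPKM and Pdcd1, which encodes PD-1, 0.156 and 0.0812, all under the filter. Cd274, which encodes the PD-1 ligand PD-L1, averaged 5.044 ± 1.545 against 5.396 ± 1.618 FPKM (adjusted p = 0.797). The alarmin S100a8, abundant in neutrophils, averaged 5.987 ± 8.762 against 29.54 ± 11.05 FPKM (adjusted p = 0.0113, and 0.0814 without the 3 libraries with atrial transcripts), and its values in aPD1_lef ran from 0.935 to 2.18 apart from 19.1 in replicate 4, without which the ratio of means was 0.0546 instead of 0.203.

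Of the 5 measured targets of the aryl hydrocarbon receptor, 1 rose, 1 fell and 3 did not pass (1 rose and 2 fell when adjusted over the list alone; adjusted p = 0.777 by camera). The median was 0.31, while the mean of -0.01 and the direction of the test were lower. Cyp1a1 (chromosome 9, 57687928 to 57703824), the enzyme most strongly induced through this receptor, was lower in aPD1_lef, at 0.6004 ± 0.5148 against 3.657 ± 1.111 FPKM, and fell by 1.57 ± 0.228 on the log2 scale (adjusted p = 0.00129). The target that rose was the quinone reductase Nqo1, by 0.31 ± 0.09 (adjusted p = 0.0237), a call that was lost without aPD1_lef replicate 3 (adjusted p = 0.0673), aPD1_veh replicate 1 (0.0502) or 2 (0.0739), and without the 3 libraries with atrial transcripts (0.0874). Dhodh, which encodes the enzyme that leflunomide inhibits, fell by 0.57 ± 0.142 (adjusted p = 0.014), from 7.577 ± 0.3623 to 4.906 ± 1.254 FPKM.

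Of 12005 genes tested with limma, 3892 changed at an adjusted p under 0.05, of which 2181 were higher and 1711 lower in the libraries labelled aPD1_lef, and 760 changed at least 2-fold. The camera test called 9 of 28 lists, 5 higher and 4 lower, none of which passed with an estimated correlation. Of these 9 lists, 7 were also called by fry, while interferon response (adjusted p = 0.0703 by fry) and sarcomere and calcium handling (0.121) were not. The median log2 change of all genes was 0.04, and 0.17 with every library scaled to one total, which gave 3467 higher and 1124 lower genes. Quantile normalization gave 1784 higher and 2205 lower genes. Without aPD1_veh replicate 2 the count was 2474 and without aPD1_veh replicate 4 it was 2379, while 4041 genes were called without aPD1_lef replicate 4 and 4245 without the 3 libraries with atrial transcripts.

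**Figure D2:**
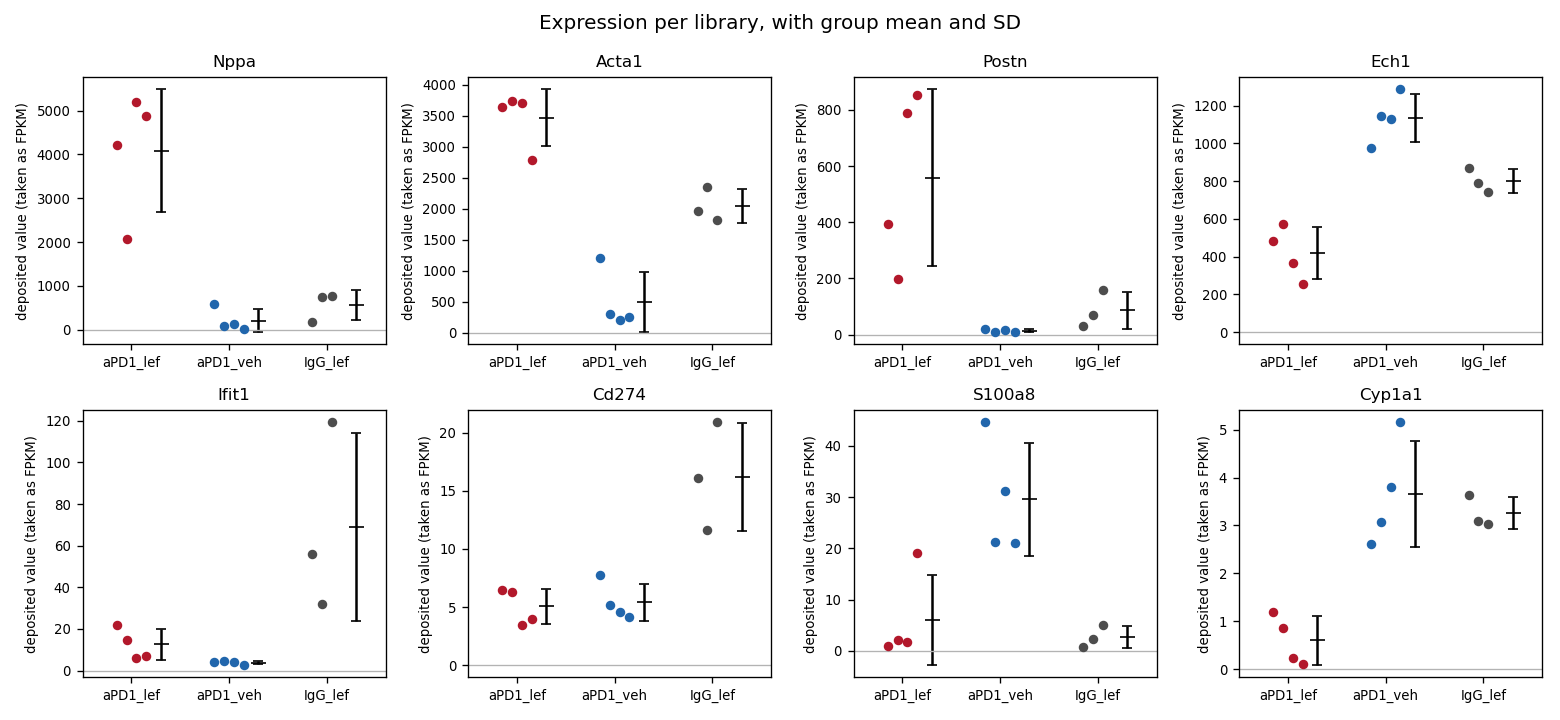
Values of 8 genes in each library, taken as FPKM, with the group mean and SD (n = 4 for aPD1_lef and aPD1_veh, n = 3 for IgG_lef). Nppa averaged 4082 in aPD1_lef, 208.6 in aPD1_veh and 570.3 in IgG_lef, while Ifit1 averaged 12.53, 3.803 and 69.09.

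The second comparison set aPD1_veh against IgG_lef, which differ, as labelled, in antibody and drug, so that no difference can be assigned to either. Of the 22 measured interferon response genes, 15 were lower in aPD1_veh than in IgG_lef, though the list did not pass with an estimated correlation (adjusted p = 0.0875). Ifit1 (chromosome 19, 34640889 to 34650009, GRCm38), which binds viral RNA, averaged 3.803 ± 0.847 FPKM (SD, n = 4) against 69.09 ± 45.16 (SD, n = 3), and Irf7, a transcription factor that amplifies the interferon response, 12.12 ± 4.784 against 99.37 ± 50.01. Cd274, itself induced by interferon, averaged 5.396 ± 1.618 against 16.2 ± 4.651 FPKM. In these 3 genes every aPD1_veh library lay below every IgG_lef library. Without IgG_lef replicate 3 the ratio of means of Ifit1 was 0.0865 instead of 0.055.

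Of 22 measured interferon response genes, 15 fell in aPD1_veh, none rose and 7 did not pass (all 22 fell when adjusted over the list alone). The median was -1.96 (adjusted p = 1.07e-38 by camera, and adjusted p = 0.0875 with an estimated correlation). Ifit1 fell by 3.68 ± 0.462 on the log2 scale (adjusted p = 0.00824), and Isg15 by 2.83 ± 0.351 and the guanylate-binding protein Gbp3 by 2.35 ± 0.267 (both adjusted p = 0.00824). Cd274 fell by 1.42 ± 0.251 (adjusted p = 0.0234). None of 13 antigen presentation genes passed over all genes (4 fell when adjusted over the list alone), although the list was lower as a whole (median -0.59, adjusted p = 6.66e-07 by camera, and adjusted p = 0.401 with an estimated correlation). The antigen presentation median was -0.363 without IgG_lef replicate 3 (adjusted p = 8.08e-06) and -0.362 without aPD1_veh replicate 4 (adjusted p = 6.7e-05). The class II chain H2-Aa averaged 62.73 ± 12.67 against 113.1 ± 39.36 FPKM. Beside these genes, 1 of 16 monocyte and macrophage markers, Fcgr1, fell and 15 did not pass (1 fell when adjusted over the list alone; median -0.47, adjusted p = 0.0029 by camera, and adjusted p = 0.615 with an estimated correlation). The macrophage median was -0.06 without IgG_lef replicate 3 (adjusted p = 0.229), -0.281 without aPD1_veh replicate 4 (adjusted p = 0.0383) and -0.736 without IgG_lef replicate 2 (adjusted p = 3.64e-06).

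Stress, matrix and fibroblast genes were lower in aPD1_veh than in IgG_lef as lists by camera, with few single genes past the threshold. By fry, the fibroblast list passed (adjusted p = 0.0364), while the stress and matrix lists did not (adjusted p = 0.479 for both). Of 19 fibrosis and matrix genes, 1 rose, 1 fell and 17 did not pass (1 rose and 4 fell when adjusted over the list alone; median -1.03, adjusted p = 0.000226 by camera, and adjusted p = 0.604 with an estimated correlation). Without IgG_lef replicate 3 this median was -0.48 (adjusted p = 0.00246). Mmp2 fell by 1.08 ± 0.15 on the log2 scale (adjusted p = 0.00846), and Mmp9 rose, from 0.282 ± 0.146 to 1.20 ± 0.0401 FPKM. Of 9 fibroblast markers, Lum fell, at 32.69 ± 4.849 against 78.47 ± 14.51 FPKM, and 8 did not pass (1 fell when adjusted over the list alone; median -0.42, adjusted p = 6.49e-05 by camera, and adjusted p = 0.209 with an estimated correlation). Of 10 cardiac stress genes, Acta1 fell, at 489.5 ± 481.4 against 2045 ± 275.5 FPKM (a ratio of 0.239, or 0.122 without aPD1_veh replicate 1), and 9 did not pass (2 fell when adjusted over the list alone; median -0.67, adjusted p = 0.0192 by camera, and adjusted p = 0.595 with an estimated correlation). This list was not called with every library scaled to one total (adjusted p = 0.0927) or without aPD1_lef replicate 4 (adjusted p = 0.0635). Nppa averaged 208.6 ± 261.6 against 570.3 ± 344.6 FPKM (adjusted p = 0.416), a ratio of 0.366, or 0.139 without aPD1_veh replicate 1. Outside the lists, Cilp fell by 2.59 ± 0.474 on the log2 scale (adjusted p = 0.026).

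Neutrophil markers were higher in aPD1_veh than in IgG_lef as a list (median 1.70, adjusted p = 0.000222 by camera, and adjusted p = 0.401 with an estimated correlation), although none of the 5 measured passed over all genes and 3 rose when adjusted over the list alone. S100a8 averaged 29.54 ± 11.05 against 2.662 ± 2.171 FPKM (adjusted p = 0.0695), a ratio of 11.1, or 19.7 without IgG_lef replicate 3. The cytokine Il1b, one of 10 inflammatory genes, rose from 0.180 ± 0.103 to 2.31 ± 1.17 FPKM and 9 did not pass (3 rose when adjusted over the list alone; median 0.32, adjusted p = 0.0192 by camera, and adjusted p = 0.615 with an estimated correlation). The inflammatory list was not called without aPD1_veh replicate 1 (adjusted p = 0.0781), without IgG_lef replicate 2 (adjusted p = 0.19) or with no filter on low values (adjusted p = 0.321). None of 19 fatty acid oxidation genes passed over all genes (4 rose when adjusted over the list alone), with a median of 0.25 (adjusted p = 3.98e-05 by camera, and adjusted p = 0.401 with an estimated correlation). Among the genes with the largest increases, Plin5, which coats lipid droplets, averaged 84.05 ± 23.33 against 37.26 ± 1.03 FPKM, and Mgll, monoglyceride lipase, 93.48 ± 15.18 against 47.55 ± 9.573. None of 6 erythroid markers passed (1 rose when adjusted over the list alone; median 0.93, adjusted p = 0.000288 by camera, and adjusted p = 0.401 with an estimated correlation), with a median of 0.29 without IgG_lef replicate 3 (adjusted p = 0.0401) and 1.42 without IgG_lef replicate 2 (adjusted p = 2.11e-08). None of 10 endothelial markers passed on either count (median 0.32, adjusted p = 0.0015 by camera, and adjusted p = 0.0875 with an estimated correlation). Cyp1a1 averaged 3.657 ± 1.111 against 3.257 ± 0.3367 FPKM (adjusted p = 0.924).

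In this comparison limma called 140 genes, 29 higher and 111 lower in aPD1_veh, against 15 higher and 131 lower with every library scaled to one total, and camera called 15 of 28 lists, 8 higher and 7 lower, none with an estimated correlation. Only 3 of these 15 lists were also called by fry: interferon response (adjusted p = 0.00521 by fry), endothelial markers (0.0196) and fibroblast markers (0.0364). The gene count depended on single libraries: it was 3 without IgG_lef replicate 3, 78 without replicate 1 and 90 without replicate 2 of IgG_lef, 86, 59, 62 and 38 without aPD1_veh replicates 1, 2, 3 and 4, and 482 without aPD1_lef replicate 4. It was 92 with no filter on low values and 389 with only the libraries of these groups fitted. The balance was nearer even with only these groups (185 higher and 204 lower) and without aPD1_lef replicate 4 (219 higher and 263 lower). Without IgG_lef replicate 3, 24 of the 25 named genes called lost their call, at adjusted p from 0.0505 to 0.272, while their log2 changes were 74.3% to 112% of those with all libraries. Ifit1 in this fit stood at -3.191, Isg15 at -2.551, Gbp3 at -2.165 and Mmp2 at -0.995.

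The third comparison, aPD1_lef against IgG_lef, asked, with the labels as they stand, what the antibody changed under leflunomide. In the libraries labelled aPD1_lef, 8 of 19 fibrosis and matrix genes were higher and 12 of 22 interferon response genes lower. Neither list passed with an estimated correlation (adjusted p = 0.672 and 0.641). The calls of single genes rest on the fit of all groups, whose estimate of spread includes aPD1_veh. With only aPD1_lef and IgG_lef fitted, limma called 0 genes. Thbs4 averaged 175.1 ± 97.43 FPKM (SD, n = 4) against 13.31 ± 8.602 (SD, n = 3), and Postn 558.4 ± 314.5 against 85.94 ± 66.06, a ratio of 6.5, or 11.2 without IgG_lef replicate 3. Ifit1 averaged 12.53 ± 7.361 against 69.09 ± 45.16 FPKM, and Cd274 5.044 ± 1.545 against 16.2 ± 4.651. Without IgG_lef replicate 3 the ratio for Ifit1 was 0.285 instead of 0.181. Nppa averaged 4082 ± 1401 against 570.3 ± 344.6 FPKM (adjusted p = 0.059, not past the threshold).

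Of 19 fibrosis and matrix genes, 8 rose, none fell and 11 did not pass (15 rose when adjusted over the list alone; median 1.73, adjusted p = 5.48e-07 by camera, and adjusted p = 0.672 with an estimated correlation). Without IgG_lef replicate 1 this median was 1.15 (adjusted p = 8.61e-07). Mmp2 rose by 1.08 ± 0.15 on the log2 scale (adjusted p = 0.00981), and Ccn2 averaged 495.2 ± 409.5 against 54.23 ± 12.04 FPKM (a ratio of 9.13, or 5.59 without aPD1_lef replicate 4). Outside the list, Thbs4 rose by 3.68 ± 0.554 (adjusted p = 0.0132) and Comp by 3.40 ± 0.66 (adjusted p = 0.0223), and Nmrk2, a muscle enzyme of NAD synthesis, averaged 121.7 ± 131 against 4.718 ± 0.9646 FPKM, a ratio of 25.8, or 12.7 without aPD1_lef replicate 3. Of 9 fibroblast markers, 4 rose and 5 did not pass (4 rose when adjusted over the list alone; median 0.43, adjusted p = 0.00335 by camera, and adjusted p = 0.641 with an estimated correlation), and this list was not called without the 3 libraries with atrial transcripts (adjusted p = 0.0688). Of 10 cardiac stress genes, 3 rose and 7 did not pass (6 rose when adjusted over the list alone; median 1.58, adjusted p = 0.00141 by camera, and adjusted p = 0.672 with an estimated correlation). Those that rose were Rcan1, a calcineurin regulator, at 137.2 ± 53.18 against 35.15 ± 7.572 FPKM, Myh7 at 533.4 ± 176.9 against 219.8 ± 21.41, and Xirp2 at 137.8 ± 69.16 against 41.08 ± 10.08.

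Of 22 interferon response genes, 12 fell, none rose and 10 did not pass (20 fell when adjusted over the list alone; median -1.28, adjusted p = 2.32e-13 by camera, and adjusted p = 0.641 with an estimated correlation). Ifit1 fell by 2.33 ± 0.462 on the log2 scale (adjusted p = 0.0237), Cd274 by 1.51 ± 0.251 (adjusted p = 0.0191) and the chemokine Cxcl9 by 1.28 ± 0.265 (adjusted p = 0.027). None of 13 antigen presentation genes passed (4 fell when adjusted over the list alone; median -0.54, adjusted p = 0.000372 by camera, and adjusted p = 0.672 with an estimated correlation), and without IgG_lef replicate 3 this median was -0.312 (adjusted p = 0.00809). Beside them, none of 16 monocyte and macrophage markers passed on either count (adjusted p = 0.371 by camera), with a median of 0.06, while the mean of -0.09 and the direction of the test were lower.

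Of 19 fatty acid oxidation genes, 4 fell, none rose and 15 did not pass (13 fell when adjusted over the list alone; median -0.74, adjusted p = 5.34e-08 by camera, and adjusted p = 0.641 with an estimated correlation). Ech1 averaged 418.4 ± 138.4 against 800.3 ± 63.25 FPKM and Hadhb, a subunit of the trifunctional protein, 406.6 ± 82.6 against 670.9 ± 46.86. Of 15 oxidative phosphorylation genes, 2 fell and 13 did not pass (15 fell when adjusted over the list alone; median -0.57, adjusted p = 3.9e-08 by camera, and adjusted p = 0.672 with an estimated correlation). None of 18 sarcomere genes passed (5 fell when adjusted over the list alone; median -0.37, adjusted p = 0.00141 by camera, 0.0775 under quantile normalization, and adjusted p = 0.672 with an estimated correlation). Without aPD1_lef replicate 4 the sarcomere median was -0.255 (adjusted p = 0.00189), and without the 3 libraries with atrial transcripts -0.595 (adjusted p = 0.000392). Ces1d (chromosome 8, 93166072 to 93197804, GRCm38) averaged 7.079 ± 7.955 against 39.94 ± 6.952 FPKM, and Inmt, an amine methyltransferase, 5.455 ± 7.135 against 36.33 ± 6.826. Without aPD1_lef replicate 2 their ratios were 0.0923 instead of 0.177 and 0.0538 instead of 0.15. Cyp1a1 fell by 1.47 ± 0.246 on the log2 scale (adjusted p = 0.0192), from 3.257 ± 0.3367 to 0.6004 ± 0.5148 FPKM.

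Here limma called 859 genes, 618 higher and 241 lower in aPD1_lef, against 652 and 538 under quantile normalization and 584 and 481 under median-ratio scaling, and camera called 11 of 28 lists, 5 higher and 6 lower, none with an estimated correlation. Only 4 of these 11 lists were also called by fry: interferon response and fatty acid oxidation (adjusted p = 0.0422 by fry for both), cardiac stress (0.0442) and fibroblast markers (0.0404). When only the libraries of these groups were fitted, limma called 0 genes, with 2603 at an unadjusted p under 0.05. The count was 2 without IgG_lef replicate 1, where all 36 named genes called lost their call at adjusted p from 0.0639 to 0.193 with log2 changes at 78.2% to 112% of those with all libraries, and 107 without replicate 2 and 369 without replicate 3 of IgG_lef. It was 229, 2276 and 31 without aPD1_lef replicates 1, 2 and 3, and 510, 311, 509 and 486 without aPD1_veh replicates 1, 2, 3 and 4. With no filter on low values it was 277, and without the 3 libraries with atrial transcripts 2081.

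**Figure D3:**
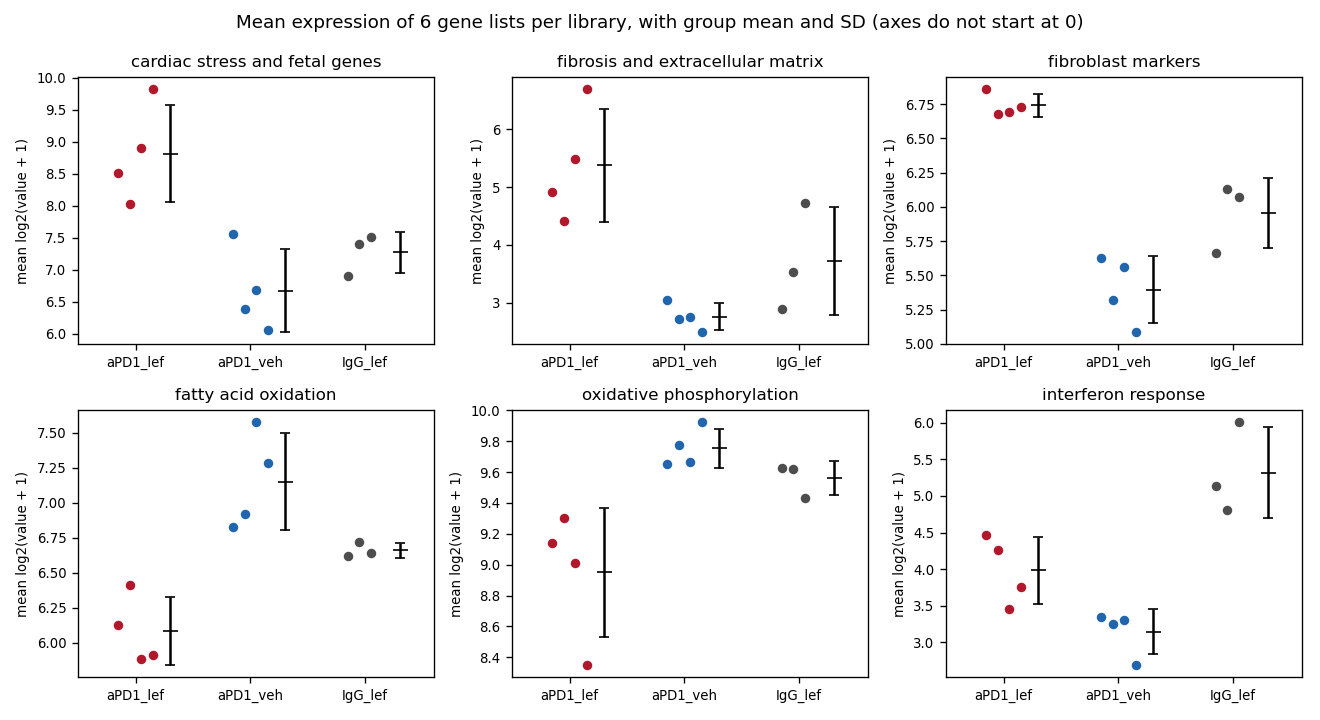
Mean log2(value + 1) of the measured genes of 6 lists in each library, with the group mean and SD (n = 4, 4 and 3) and axes that do not start at 0. The interferon score lay between 2.69 and 3.34 in aPD1_veh and between 4.81 and 6.01 in IgG_lef.

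Genes that set aPD1_veh apart from both other groups were counted across the first and second comparisons, which share the aPD1_veh libraries. In all, 110 genes were called in both on the same side, 24 higher and 86 lower in aPD1_veh, and 0 on opposite sides. Without IgG_lef replicate 3 the second comparison called only 3 genes, and without aPD1_veh replicate 4 only 38, so the size of the overlap depends on single libraries. Of the 25 named genes called in the second comparison, 24 lost their call without IgG_lef replicate 3. Their log2 changes were then 74.3% to 112% of those with all libraries. Isg15, Oas1a, Bst2, Fcgr1, Lum, Mmp2, Cilp and Acta1 were among the 86. Independent lists of these sizes would share 4.13 higher and 20.17 lower genes, which does not allow for the shared libraries. With the aPD1_veh libraries split so that each comparison used its own pair, the overlap was 0 to 13 genes. These fits called only 0 to 28 genes against IgG_lef, so few could overlap. The covariance of the log2 changes was 0.112 against 0.02 in 50 simulations of unchanged groups with the same shared libraries, and 0.088 to 0.116 in the split libraries. Their correlation was 0.624 against 0.462 in the simulations, and 0.454 to 0.618 in the split libraries. The simulations drew each gene independently, with the same spread in every group. They therefore cannot show how far these measures vary by chance in these data, where genes are correlated.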

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

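The tests of atrial tissue, fibroblasts, exchanged labels, macrophages, single libraries and time of day were chosen only after the results were seen, while the regroupings of libraries and the test of transcript length were chosen before. Of the 35 ways to divide the 8 libraries of aPD1_lef and aPD1_veh, 1, the real one, called as many genes (3892, with 0 as the highest of the others). For aPD1_veh and IgG_lef it was also 1 of 35 (140 genes, with 1 as the highest of the others). This argues against a chance division in both, at the smallest share that 35 divisions allow and without adjustment over the comparisons. It does not tell the treatment from anything else shared within a group. Without IgG_lef replicate 3 the second count was 3. For aPD1_lef and IgG_lef, 2 of 35 divisions called as many, the real one with 859 genes and another with 2110, so chance cannot be excluded. The other division grouped aPD1_lef replicate 2 with the 3 IgG_lef libraries, and its count points to a structure of the samples, of which no test shows more. With the labels kept and this library left out, 2276 genes were called, 829 of the 859 among them with the same sign.

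Of the listed stress and matrix genes, 8 of 10 and 15 of 19 were higher in the libraries labelled aPD1_lef than in aPD1_veh, and 1 matrix gene was lower. Neither list passed by camera with an estimated correlation (adjusted p = 0.663 for both). Atrial tissue in the samples is argued against as the source of Nppa, because the lower Nppa value of the 2 aPD1_lef libraries with Myl7 under 1 was 8.17 times the highest aPD1_veh value. The median log2 change of the matrix genes exceeded that of the fibroblast markers by 1.98 (permutation of genes, p = 0.031). The permutation treats genes as independent, while the estimated correlation was 0.742 within the matrix list and 0.208 within the fibroblast list. Its p-value therefore does not measure the spread between samples, and it cannot decide on a larger share of fibroblasts. A change within fibroblasts also stays open. An exchange of the labels of these groups cannot be told apart from an effect of leflunomide on the heart, which was not tested: Cyp1a1 changed by -1.57 (adjusted p = 0.0013), but the called targets of its receptor lay on both sides of 0. The groups labelled as given the drug differed in Cyp1a1, at 3.257 FPKM in IgG_lef and 0.6004 in aPD1_lef (adjusted p = 0.0192 by limma). In aPD1_veh it stood at 3.657 (adjusted p = 0.924 against IgG_lef), which an exchange would also give. Nqo1, the called target that rose, went the other way, at 46.68 FPKM in aPD1_lef and 49.87 in IgG_lef against 37.27 in aPD1_veh. Each pattern is that of 1 gene, and the antibody differs too.

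Of 22 measured interferon response genes, 15 were higher in IgG_lef than in aPD1_veh and 12 were higher than in aPD1_lef. The list did not pass by camera with an estimated correlation (adjusted p = 0.0875 and 0.641). The median log2 change of interferon genes differed from that of macrophage markers by -1.49 in aPD1_veh against IgG_lef (permutation of genes, p = 0.00089). In aPD1_lef against IgG_lef it differed by -1.33 (permutation of genes, p = 2e-05). The interferon genes thus changed by more than these markers in these samples. The permutation treats genes as independent, while the estimated correlation was 0.708 within the interferon list and 0.715 within the macrophage list. Its p-values therefore do not measure the spread between samples, and it cannot decide on a larger share of monocytes and macrophages. IgG_lef replicate 3 alone is argued against as the source, because the lower interferon score of IgG_lef replicates 1 and 2 still exceeded the highest aPD1_veh score by 1.47 and the highest aPD1_lef score by 0.35 on the log2 scale, although calls of single genes were lost without replicate 3. An effect of the antibody stays open and was not tested, and aPD1_veh against IgG_lef also differs in drug.

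Replicate 4 of aPD1_lef lay apart from the other libraries, with 48.97 FPKM of the immediate early gene Fos against 0.81 to 3.89 elsewhere and 249.1 FPKM of the acute-phase gene Lcn2 against 2.90 to 30.4 (genes chosen after their values were seen). A loss of long transcripts is argued against, because its deviation from its group correlated with exon length across genes at only rho = 0.046 (0.038, -0.018 and -0.129 in replicates 1, 2 and 3). Another time of day at harvest cannot be told apart from acute stress or handling of this heart, which were not tested: the clock score, the mean of Arntl, Clock and Cry1 minus that of the 11 other clock genes measured, was -0.79 in this library and -2.43 to -1.38 in the other 10, but of those 11 genes 6, such as Per1 (47.71 FPKM), were at their highest here and 5, such as Dbp (10.83 FPKM), at their lowest. Among the other 10 libraries the clock score also differed by group. It was -1.994 to -1.375 in aPD1_veh, -2.398 to -2.285 in IgG_lef and -2.429 to -1.711 in aPD1_lef replicates 1 to 3. Whether harvest times differed between the groups was not tested. A first version of this score used fewer clock genes, picked after their values were seen, and was replaced by all measured genes of the list.

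Among 338 sets of 4 replicate values (named genes and list scores), 22 had a highest or lowest value whose gap to the nearest other exceeded Dixon's critical value as a share of the range, against 16.9 by chance, and 9 of the 22 concerned aPD1_lef replicate 4. In that library the share was 0.965 for Cyp1b1 (24.9 FPKM against 3.46 to 4.2), 0.958 for Tiparp (34.8 against 3.02 to 4.34), 0.91 for Junb (164 against 15.5 to 29), 0.867 for Thbs1 (195 against 13.2 to 37.3) and 0.906 for Acta1 (2780 against 3640 to 3730). For genes of immune cells it was 0.988 for S100a9 (24 FPKM against 1.32 to 1.59), 0.931 for S100a8 (19.1 against 0.935 to 2.18), 0.879 for Ccl5 (5.9 against 1.64 to 2.16) and 0.879 for Ly6c2 (13.2 against 5.94 to 6.82). In aPD1_lef replicate 3 it was 0.84 for Mcm5 (4.72 FPKM against 3.16 to 3.41), and in replicate 2 it was 0.834 for Pi16 (111 against 129 to 132) and 0.864 for Fah (8.87 against 6.15 to 6.52). In aPD1_veh replicate 1 it was 0.893 for Acta1 (1210 FPKM against 198 to 306), 0.869 for Xirp2 (36.1 against 19.3 to 21.5), 0.925 for Rcan1 (60.1 against 33.8 to 35.7), 0.882 for Lum (39.9 against 29.7 to 30.9), 0.875 for Pcolce (46.6 against 30.5 to 32.5) and 0.929 for Csf3r (3.04 against 1.87 to 1.96). In aPD1_veh replicate 3 it was 0.947 for Ly6c2 (15.4 FPKM against 6.93 to 7.38) and 0.862 for Cat (150 against 96.6 to 104). In aPD1_veh replicate 4 it was 0.876 for Efnb3 (49.3 FPKM against 29.1 to 31.6) and 0.871 for the interferon list score (2.69 against 3.26 to 3.34). IgG_lef, with 3 libraries, was not tested in this way. The 16.9 given for chance assumes independent sets of normally distributed values. Here the sets of a group share its libraries and gene values were not on a log scale, so 22 against 16.9 does not show an excess.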

How the results depend on the processing

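Median-ratio scaling and leaving out the 3 libraries with atrial transcripts were chosen only after seeing the data. The alternatives planned for read counts (another tool, other size factors, library size alone and a stricter count filter) were not run, because the table held no counts, and a fit without trend, quantile normalization, scaling to one total and a pseudocount of 0.1 took their place. In aPD1_lef against aPD1_veh, 50 of 56 named genes called and 8 of 9 lists kept their call and direction in every setting run that measured them, apart from camera with an estimated correlation and fry for the lists. A gene under the filter in a setting was not counted there, which left 54 genes without the 3 libraries with atrial transcripts and 55 in some other settings. In aPD1_veh against IgG_lef 0 of 25 genes and 8 of 15 lists did, and in aPD1_lef against IgG_lef 0 of 36 genes and 6 of 11 lists. No called named gene changed sign. With 1 library left out, limma called 2379 to 4264, 3 to 482 and 2 to 2276 genes in the 3 comparisons in that order, against 3892, 140 and 859. With no filter it called 92 genes in aPD1_veh against IgG_lef and 277 in aPD1_lef against IgG_lef, where more genes are tested. With only the groups compared it called 389 and 0 (2603 at an unadjusted p under 0.05), and without the libraries with atrial transcripts 2081 in aPD1_lef against IgG_lef. Camera with an estimated correlation called 0, 0 and 0 lists, against 9, 15 and 11 with the preset one, and fry called 10, 3 and 5. In the fit of only aPD1_lef and IgG_lef, all 36 named genes called lost their call, at adjusted p from 0.076 to 0.147 by limma. Their log2 changes were 100% of those in the fit of all groups, so their estimated spread and the set of genes tested differed. The cause of the other shifts was not tested.

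Replicate numbers did not pair the libraries: 4 of 10 pairs with the same number correlated above 0.1 (range -0.29 to 0.194, median -0.043, against 0.038 for other pairs). With the replicate number as a block, limma called 3602 genes in aPD1_lef against aPD1_veh, 0 in aPD1_veh against IgG_lef (1494 at an unadjusted p under 0.05) and 0 in aPD1_lef against IgG_lef (2830), and the overlap was 0 instead of 110. With the aPD1_veh libraries split 2 against 2 the mean overlap was 4.5, where fewer samples enter each comparison.

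Some genes not called changed sign. In aPD1_lef against aPD1_veh, Ccl5 (-0.109) was 0.001 scaled to one total and 0.257 without the libraries with atrial transcripts, and -0.419 to 0.042 with 1 library left out. Cd274 (-0.087) was 0.037 scaled to one total and -0.199 to 0.074 with 1 left out. In aPD1_veh against IgG_lef, Cyp1b1 (-0.005) was 0.056 and Myh6 (0.158) was -0.043 under quantile normalization. Ccl5 (0.056) was -0.013 and Tiparp (0.042) -0.027 scaled to one total, -0.082 and -0.299 with the replicate block, and Ccl5 was -0.277 without the libraries with atrial transcripts. With 1 left out, Ccl5 ran from -0.277 to 0.366, Cyp1a1 from -0.041 to 0.217, Cyp1b1 from -0.1 to 0.118 and Tiparp from -0.085 to 0.18. In aPD1_lef against IgG_lef, Ccl5 ran from -0.386 to 0.256 and Tiparp from -0.027 (without aPD1_lef replicate 4) to 1.025. The cause was not tested. The unknown depth leaves the precision of genes near the filter open.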

Other observations

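The genes of this paragraph were chosen from the fixed lists after their values were seen. Of 15 measured genes of pyrimidine synthesis and salvage, 6 rose, 2 fell and 7 did not pass in aPD1_lef against aPD1_veh (7 rose and 2 fell when adjusted over the list alone; adjusted p = 0.0596 by camera). The uridine kinase Uck2, which salvages uridine, averaged 91.33 ± 66.45 against 16.84 ± 4.889 FPKM and rose by 2.10 on the log2 scale (adjusted p = 0.00681 by limma), and Rrm2, a subunit of ribonucleotide reductase, 3.289 ± 1.401 against 0.991 ± 0.215. Of 12 genes of PI3K, AKT and FOXO signalling, 1 rose, 4 fell and 7 did not pass (2 rose and 4 fell when adjusted over the list alone; adjusted p = 0.176 by camera). The growth factor Igf1 averaged 7.302 ± 1.593 against 2.169 ± 0.2394 FPKM, and Klf15, a transcription factor of cardiac metabolism, 13.45 ± 1.804 against 29.08 ± 7.146. Of 12 p53 targets, 4 rose, 1 fell and 7 did not pass (4 rose and 1 fell when adjusted over the list alone; adjusted p = 0.0753 by camera), with Phlda3, an inhibitor of AKT, at 28.03 ± 4.424 against 9.709 ± 1.754 FPKM. Of 19 glycolysis genes, 5 fell and 14 did not pass (4 fell when adjusted over the list alone; adjusted p = 0.347 by camera), and the insulin-responsive glucose transporter Slc2a4 averaged 80.63 ± 35.72 against 173.5 ± 15.93 FPKM. Of 14 clock genes, 5 rose and 9 did not pass (5 rose when adjusted over the list alone; adjusted p = 0.264 by camera), among them Nr1d1, a repressor of the clock, at 47.66 ± 11.83 against 24.96 ± 5.047 FPKM.

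Some lists were called by camera without any member past the threshold, over all genes or over the list alone. In aPD1_veh against IgG_lef, glycolysis (19 genes, median 0.18, adjusted p = 0.0121, and adjusted p = 0.285 with an estimated correlation), oxidative phosphorylation (15 genes, median 0.20, adjusted p = 0.0158 and 0.769) and NRF2 and antioxidant genes (12 genes, median 0.18, adjusted p = 0.0379 and 0.401) were higher, and proliferation genes (10 genes, median -0.34, adjusted p = 0.0115 and 0.604) were lower. None of these 4 was called without IgG_lef replicate 3 (adjusted p = 0.071, 0.33, 0.178 and 0.312), oxidative phosphorylation was not called without aPD1_veh replicate 4 (0.157), and NRF2 genes were not called without aPD1_veh replicate 1 (0.0552) or 3 (0.14). The NRF2 median was 0.045 without aPD1_veh replicate 3, and the proliferation median -0.044 without IgG_lef replicate 3 and -0.518 without IgG_lef replicate 1. Under quantile normalization glycolysis (0.28), oxidative phosphorylation (0.936) and NRF2 genes (0.261) were not called.

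In aPD1_lef against IgG_lef, the same held for immediate early and heat shock genes (13 genes, median 0.86, adjusted p = 0.0125, and adjusted p = 0.672 with an estimated correlation) and proliferation genes (10 genes, median 0.51, adjusted p = 0.0223 and 0.672), which were higher, and for erythroid markers (6 genes, median -0.68, adjusted p = 0.0471 and 0.672), which were lower. Immediate early genes were not called without aPD1_lef replicate 4 (0.173) or IgG_lef replicate 3 (0.0786). Proliferation genes were not called without aPD1_lef replicate 3 (0.0542) or 4 (0.172) or IgG_lef replicate 1 (0.0521) or 2 (0.126), and without IgG_lef replicate 3 their median was 0.897 (0.00281). Erythroid markers were not called without aPD1_lef replicate 1 (0.0796), 2 (0.1), 3 (0.0542) or 4 (0.0593), aPD1_veh replicate 1 (0.0507) or IgG_lef replicate 1 (0.162) or 2 (0.466), and their median was -0.191 without IgG_lef replicate 2 and -1.317 without replicate 3 (9.37e-08).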
